A study of Mus musculus with 16 samples.

How the data were processed

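Livers of Gcn2 wild-type mice and of littermates lacking Gcn2 were perfused in a single pass, either with a medium holding all amino acids or with one from which methionine was omitted. RNA was taken from the liver supernatant before any gradient (unfractionated RNA) and from the polysome part of a sucrose gradient, where mRNAs that carry several ribosomes sediment. Per the labels, RNA of 2 livers was pooled for each Affymetrix array and the labelling was one-cycle with biotin. Genotype, medium and RNA fraction define 8 groups of 2 arrays, 16 arrays in all, so each replicate is a pool of 2 livers. All groups were taken from the titles and source names, and 0 columns of the value tables were left without a sample.

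The deposited value table gives each probe set's intensity as a linear Affymetrix signal for 45101 probe sets. The authors' signal algorithm is not given in the sources used here. The mean signal after trimming 2% of probe sets at each end was 150.0 in every array, so all arrays had been scaled to one mean. A second deposited table gives, per the file headers, a z score for each array and z ratios, each a score for the difference between a pair of groups, for 15709 probe sets with a signal of 80 or more in at least 1 array. Both were rebuilt from the deposited signals to within 0.0005. The z ratio divides a difference of group means by the SD of that difference across probe sets, and no replicate error enters it. The z ratios served as a comparison alone.

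Array medians of the deposited signal ran from 18.3 to 27.7, further apart than the 10% allowed by a rule set beforehand. By that rule each array was divided by the ratio of its median to the mean of the medians, which shifted single arrays by -0.29 to 0.31 on the log2 scale. The medians lay among dim probe sets, as 26.9% to 28.5% of probe sets per array reached a signal of 80. The tests of genes and lists and the correlations of methionine effects were therefore also computed from the signals as deposited, an alternative added after the medians were seen. Log2 values were taken after adding 16, which shrinks the fold changes of dim genes.

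Probe sets were joined to genes by the supplied probe annotation, with symbols checked through gene identifiers in a table of RefSeq genes (assembly GRCm38.p6), and 0 of the 34741 probe sets looked up changed symbol. Among 34945 probe sets with 1 symbol, the one with the highest mean over all arrays stood for its gene, which gave 18193 genes, 9010 of them with more than 1 probe set. Left out were 932 probe sets with several symbols, 9211 without one and 13 control probe sets. The dimmest 40% of genes were not tested, which left 10916. The files name no genome build for the probes, so gene order came from the assembly and positions are not given.

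Differences were tested with limma 3.58.1 in R 4.3.3, on the means of all 8 groups, with moderated variances that follow the mean signal (eBayes with trend, 8 residual degrees of freedom, two-sided). P-values were adjusted by Benjamini and Hochberg over the genes tested within a comparison, with a threshold of 0.05. The 11 comparisons were the effect of omitting methionine (without minus with) in each genotype and fraction, its difference between genotypes (knockout minus wild-type) in each fraction, the polysome-specific effect (effect in polysome RNA minus effect in unfractionated RNA) in each genotype and its difference, knockout minus wild-type over all arrays, and polysome minus unfractionated over all arrays. Fold changes are log2 with standard errors from the fit.

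The members of 41 gene lists were fixed, and 37 lists with at least 4 tested members entered limma's camera test with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera asks whether a list moves relative to the other genes. Camera with an estimated correlation and fry, which asks whether a list moves one way on balance, were run beside it. The other 4 lists held fewer tested members and were not set-tested. Named genes were the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between groups (comparisons of a pair of groups), or all where fewer passed. Where no gene passed, the 5 smallest p-values in each direction were taken. The rule added up to 4 members of each list that passed, and a fixed set of genes of the amino acid response and lipid synthesis. Beyond about 30 genes a comparison, counts were given. The comparisons, tests, lists and naming rule were chosen before the data were examined.

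Whether the replicate numbers pair the arrays was checked from the data. Unfractionated and polysome arrays with the same genotype, medium and number shared deviations from their group means, with correlations across genes of 0.231, 0.205, 0.322 and 0.169. The numbers were therefore taken to pair the fractions of a pool, which the labels do not state. The pairing is an inference, as arrays of different livers reached similar values. Across media the correlations had a median of -0.02 and across genotypes of 0.04, but knockout unfractionated arrays with and without methionine reached 0.259 and wild-type and knockout unfractionated arrays without methionine 0.133. No pairing was used there, as the other such pairs of groups lay between -0.06 and 0.05, and a fit with the replicate number as a block was run as an alternative. Groups that differed in 2 or 3 factors ran from -0.07 to 0.15. Among them were wild-type unfractionated arrays without and knockout unfractionated arrays with methionine (0.140). A fit with the pool as a random block (correlation 0.103) called 269 genes for the methionine effect in wild-type polysome RNA, 245 for genotype and 2682 for polysome minus unfractionated.

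The alternatives tried were other scalings, other offsets, other filters, other ways to choose probe sets, the replicate number or the pool as a block, no variance trend, a threshold of 0.1, subsets of arrays and leaving out each array in turn. The procedure was tested on simulated data with 100 genes changed 4-fold and 100 changed 2-fold. The simulated noise was independent between arrays and genes, without shared deviations, so recovery in the real arrays may be lower. At a 4-fold change the procedure recovered 86% of the genes for the methionine effect in wild-type unfractionated RNA and 89% in wild-type polysome RNA. It recovered 49% and 53% for the differences between genotypes, and 5% for the polysome-specific difference between genotypes. At a 2-fold change it recovered 43%, 18%, 2%, 5% and 0%. For the methionine effect in knockout livers it recovered 22% in unfractionated and 19% in polysome RNA. Each figure came from a single simulated draw, with the same noise per gene in every group. Gaps among the methionine effects of single genotypes and fractions therefore do not show a difference in sensitivity.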

Results

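The series measured mRNA levels in perfused mouse liver with 16 Affymetrix arrays. Gcn2 (gene Eif2ak4) is a kinase that senses uncharged tRNA and phosphorylates eIF2, which lowers translation in general and favours mRNAs such as that of the transcription factor ATF4. Livers of wild-type and Gcn2 knockout mice were perfused with or without methionine, and each was measured as unfractionated RNA and as polysome RNA, which gave 8 groups with 2 arrays each, every array a pool of 2 livers. The number of arrays limits the precision. Of 45101 probe sets, 26.9% to 28.5% reached a signal of 80 in an array, replicate arrays correlated at 0.968 to 0.976 across genes, and 10916 genes were tested. Fold changes are log2, after adding 16 to the signal, with the SE of the fit. Lists of genes were tested with camera, and 0 of the 118 list shifts that passed with the preset correlation passed with an estimated one.

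The comparison of knockout with wild-type livers asks what loss of Gcn2 does at either methionine supply. Eif2ak4 itself was lower in knockout livers by a log2 fold change of -0.89 ± 0.17 (SE, 8 arrays per genotype, adjusted p = 0.0035). The 8 arrays count both fractions of each pool, and with the pool as a random block its adjusted p was 0.0055. Its signal in unfractionated RNA with methionine was 104.2 ± 14.8 (SD, n = 2) in wild-type and 42.8 ± 6.2 (SD, n = 2) in knockout livers, but 60.4 ± 12.8 and 50.6 ± 1.6 (SD, n = 2 each) in polysome RNA without methionine, and where its probes lie relative to the deletion is not given in the sources used here. The call was lost with arrays without methionine alone (-0.62, adjusted p = 0.27), with polysome arrays alone (-0.74, 0.15) and with the mean of its probe sets (-0.45, 0.079). Asns, which encodes asparagine synthetase and is a classical ATF4 target, fell much further, by a log2 fold change of -3.35 ± 0.17 (adjusted p = 7.4e-12), from a signal of 924.7 ± 168.5 (SD, n = 2) to 67.0 ± 11.9 (SD, n = 2) in unfractionated RNA with methionine. Trib3, a pseudokinase induced by ATF4, fell by 0.85 ± 0.18 (adjusted p = 0.0081), and Chac1, a glutathione-degrading enzyme also induced by ATF4, rose by 0.72 ± 0.15 (adjusted p = 0.0086), and lies near Gcn2 on its chromosome.

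Not every gene of the amino acid response differed between genotypes. Of 28 tested ATF4 targets, 1 rose and 3 fell, or 1 and 5 when adjusted over the list alone, and the list did not pass (median -0.17, adjusted p = 0.070). Atf4 mRNA had a log2 fold change of -0.01 ± 0.13 (adjusted p = 0.99), and Ddit3 (-0.22), Atf3 (-0.80, adjusted p = 0.14) and Fgf21 (-0.87, adjusted p = 0.22) did not pass either. Psat1 and Sesn2 were too dim to be tested.

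**Figure D1:**
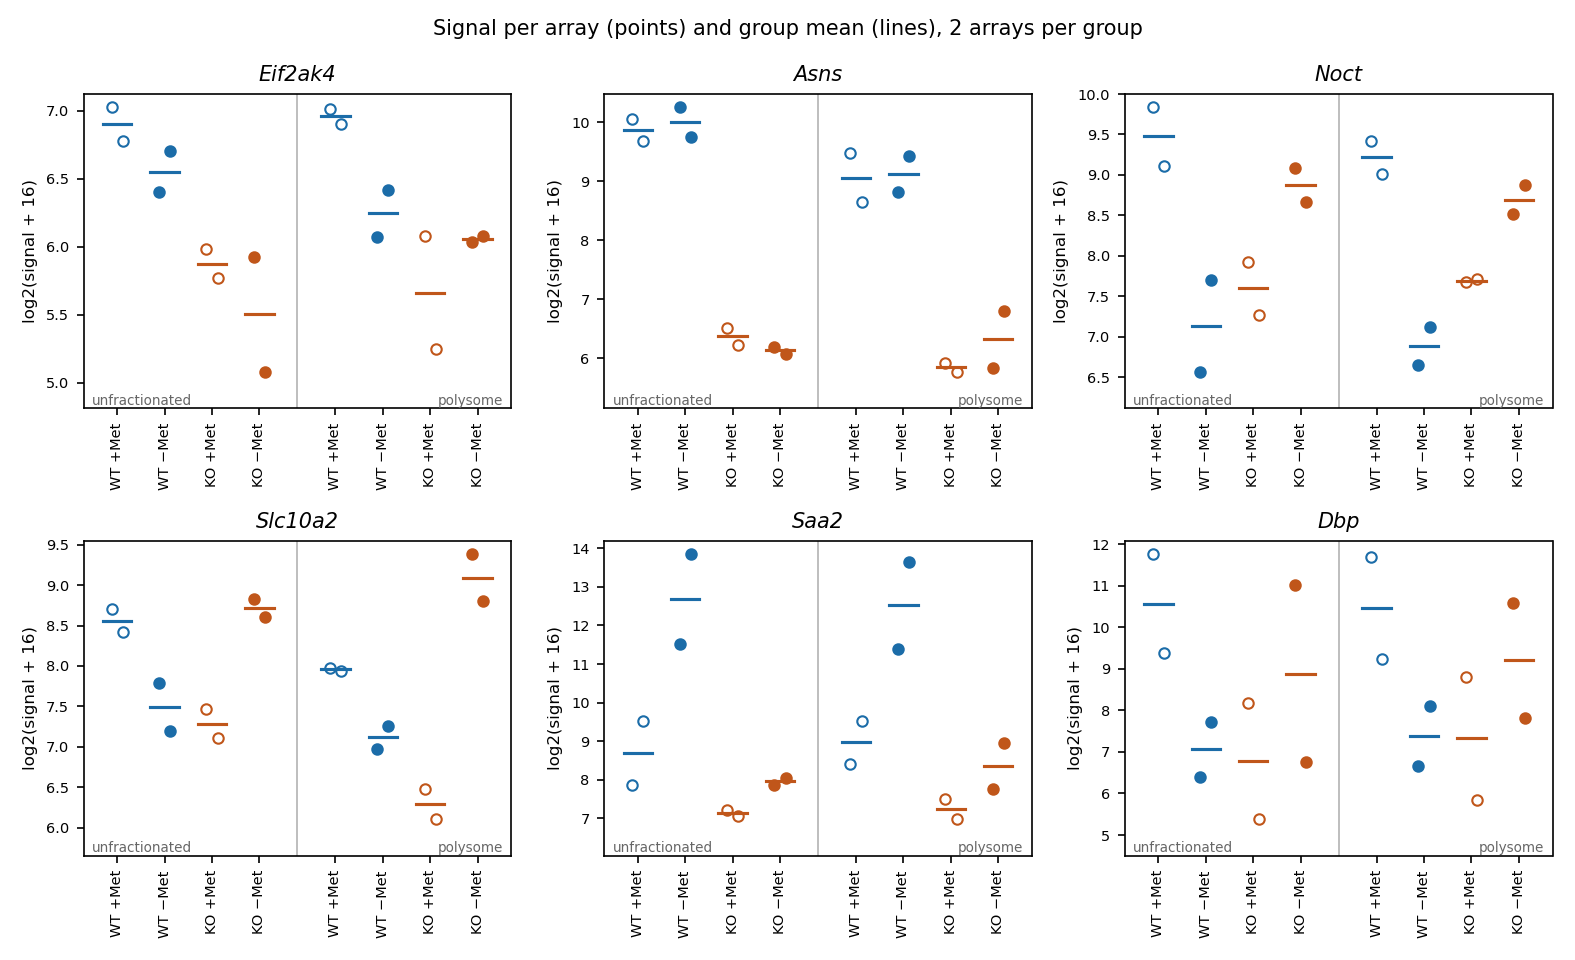
Log2(signal + 16) of Eif2ak4, Asns, Noct, Slc10a2, Saa2 and Dbp in each of the 16 arrays, in 8 groups of 2 (blue wild-type, orange knockout, open with methionine, filled without, line for the group mean). Asns was lower in the knockout arrays by 3.35, Noct was lower without methionine in wild-type livers by 2.35 in unfractionated RNA, and the 2 arrays of a group lay far apart for Dbp.

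Other large differences between genotypes lay outside the amino acid response. Dct, a melanin synthesis enzyme, was lower by -4.41 ± 0.20 (adjusted p = 1.5e-12), with a signal of 654.7 ± 242.7 (SD, n = 2) in wild-type and 6.89 ± 3.69 (SD, n = 2) in knockout unfractionated RNA with methionine. Cyp2c39, a cytochrome P450 in a block where 7 of 8 tested genes differed, was higher by 3.67 ± 0.16 (adjusted p = 1.5e-12), and so were Ighm, the heavy chain of immunoglobulin M (3.27 ± 0.30), and A2ml1 (3.07 ± 0.16). Further falls were those of the acute phase protein Saa2 (-3.04 ± 0.33), Hddc3 (-3.00 ± 0.19), the protease Ctse (-2.95 ± 0.41), Mt1 (metallothionein, -2.25 ± 0.37), Sugct (-2.20 ± 0.21), Lcn2 (-2.11 ± 0.45) and Cfap126 (-2.10 ± 0.20). Cyp2c37 (-2.33 ± 0.57) was called with an adjusted p of 0.028, but not with the signals as deposited (0.057) or quantile normalization (0.058), nor without any 1 of 8 arrays (0.054 to 0.074). Zfp874a, Abhd1, Clec2h, Obp2a, Asic5, Pik3ap1 and Rbm45 rose by 1.75 to 2.36.

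Among the lists fixed beforehand, 1 stood higher in knockout livers and 12 lower, relative to all genes. In the acute phase list 4 of 20 tested members fell (9 adjusted over the list alone; median -0.33, adjusted p = 1.2e-05), Saa1 by -2.08 ± 0.28 and haptoglobin (Hp) by -0.59 ± 0.13. All 13 tested markers of Kupffer cells, the macrophages of the liver, had negative fold changes, or 12 of them with the signals as deposited (median -0.32, adjusted p = 3.3e-05), and 1, Cd5l (-1.24 ± 0.14), passed. Proteasome subunits (median -0.25), tRNA synthetases (-0.23), targets of the fatty acid sensor PPARA (-0.25), immediate early genes (-0.27) and interferon response genes (-0.32) stood lower. Male-biased genes also stood lower (-0.30, with Cyp4a12a and Hsd3b5 lower, but Hsd3b5 at 0.017 in arrays without methionine alone). So did urea cycle and amino acid catabolism (-0.20), and, lost without some single arrays, heat shock (-0.19, Hspa1b lower), serine and one-carbon metabolism (-0.20) and gluconeogenesis (-0.21). Ribosomal protein mRNAs stood higher (median 0.13, adjusted p = 2.8e-05, 0 of 42 called). All 13 lists were lost with an estimated correlation (adjusted p 0.77 to 0.78). Heat shock was lost without replicate 2 with methionine of wild-type unfractionated (-0.15) or polysome RNA (-0.24), serine and one-carbon metabolism without any 1 of 3 arrays (-0.20 to -0.15) and gluconeogenesis without any 1 of 5 (-0.21 to -0.15), while the other 10 lists held without any 1 array. Single members of these lists were called less firmly, as Kmo was lost without any 1 of 13 arrays, Hadha of 12, Haao of 10, Fosb of 7, Gpt2 of 6 and Hp of 1. Without replicate 1 with methionine of wild-type unfractionated or polysome RNA, Gpt2 was called through another probe set that became its brightest. With its first probe set kept it was lost there too (-0.54 and -0.51).

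By limma, 276 genes differed between genotypes, 91 higher and 185 lower in knockout livers. This fit takes both fractions of a pool as independent, and with the pool as a random block 86 were higher and 159 lower. With the signals as deposited 221 were higher and 235 lower, with quantile normalization 243 and 255, and 90 higher and 177 lower genes were called both as deposited and with the scaling used here. Unfractionated arrays alone called 24 higher and 55 lower genes, and arrays with methionine alone 40 and 96, but polysome arrays alone called 94 higher and 61 lower, and arrays without methionine alone 83 and 67. Without both wild-type polysome arrays lacking methionine, which stood apart from the others, 58 were higher and 142 lower.

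In wild-type livers the comparison without and with methionine asks how the liver responds to the loss of 1 essential amino acid. In unfractionated RNA, mRNAs of the acute phase proteins, which the liver secretes in inflammation, stood higher without methionine. Saa2 rose by 3.98 ± 0.65 (SE, 2 arrays per group, adjusted p = 0.015), from a signal of 468.9 ± 356.8 (SD, n = 2) to 8790 ± 8331 (SD, n = 2), so the replicate pools differed widely. Noct, a rhythmic phosphatase once described as a deadenylase, fell by -2.35 ± 0.35 (adjusted p = 0.011), from 720.2 ± 257.7 to 135.2 ± 79.6 (SD, n = 2 each). The classical ATF4 targets did not pass, with Asns at 0.14 ± 0.33, Trib3 at -0.88 ± 0.36, Ddit3 at -0.42 ± 0.32, Atf3 at -0.39 ± 0.54, Chac1 at 0.86 ± 0.30 (adjusted p = 0.82) and Fgf21 at -1.77 ± 0.66.

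The other genes called were Saa1 (2.93 ± 0.56), Apcs (serum amyloid P, 2.44 ± 0.43), Gm7969 (2.48 ± 0.39), Asic5 (1.85 ± 0.31) and Adh6-ps1 (1.85 ± 0.35), which rose, and Meiob (-1.43 ± 0.24), which fell. As the median of all genes was -0.13, list medians are also given relative to it. All 20 acute phase genes had positive fold changes (median 0.66, or 0.79 relative to all genes, adjusted p = 1.3e-27), 3 passed, and 11 passed adjusted over the list alone. With an estimated correlation their adjusted p was 0.17. Secreted plasma proteins stood higher (median 0.34 relative to all genes, 27 of 28 positive, 0 called, adjusted p = 1.6e-09), as did cytochrome P450 and other drug metabolism genes (0.39). Clock genes that peak with Dbp stood lower (median -0.91, 4 of 9 lower adjusted over the list alone, adjusted p = 0.00029) and those that peak with Bmal1 higher (0.71, adjusted p = 8.3e-05, lost without replicate 1 without methionine, 0.37). In all 8 pairs of arrays of one group these clock lists also differed in opposite directions between the arrays. Among them neither Dbp (-3.51 ± 1.18, adjusted p = 0.78) nor Per1 (-1.67 ± 0.38, adjusted p = 0.19) passed. A further 5 lists passed but were lost without single arrays, given as plain medians. Cholesterol synthesis (0.08) was lost without replicate 1 with (-0.045) or without methionine (-0.087), and cell cycle (0.21) without replicate 2 with (-0.004) or without it (0.022). Heat shock (-0.36) was lost without replicate 2 with (-0.31) or without it (-0.45). Female-biased genes (0.23, lost as deposited, adjusted p = 0.16) were lost without any 1 of 7 arrays (0.18 to 0.26), and amino acid transporters (-0.01, higher relative to all genes) without any 1 of 4 (-0.03 to 0.07). All 10 lists were lost with an estimated correlation (adjusted p 0.17 to 0.91). ATF4 targets did not pass (median -0.19, adjusted p = 0.29).

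By limma, 8 of 10916 genes passed, 6 higher and 2 lower, with 517 at an unadjusted p under 0.05. With the signals as deposited 5 were higher and 2 lower, and Saa2 (adjusted p = 0.059), Saa1 (0.11) and Adh6-ps1 (0.060) were lost. Without wild-type unfractionated replicate 1 with methionine 0 genes passed, and without replicate 2 with methionine or replicate 2 without it 3 passed. Saa2 was not called without replicate 1 with methionine (3.15) or replicate 2 without it (2.82), nor Noct without replicate 1 with methionine (-1.98) or replicate 1 without it (-1.78). The other called genes were lost without any 1 of 3 to 10 arrays.

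In knockout livers the same comparison asks what remains of the response when Gcn2 is absent. In unfractionated RNA, limma called 0 genes, with 418 at an unadjusted p under 0.05. Replicate arrays lay further apart here, with a median absolute log2 difference of 0.404 with and 0.371 without methionine. In wild-type unfractionated RNA it was 0.238 and 0.270, so the lack of calls does not show a lost response. The smallest p-values upward, none called, were those of Slc10a2, the ileal type bile acid transporter (1.43 ± 0.28, adjusted p = 0.51), Noct (1.28 ± 0.35), Svil (1.15), Gm4951 (1.37) and Wbscr25 (1.67), and downward those of Lce1h (-1.96), Lrtm1 (-1.84), Gm13889 (-1.23), Mul1 (-1.19) and the methylmalonyl-CoA mutase gene Mmut (-1.14). Asns had a log2 fold change of -0.24 ± 0.33, Atf4 0.46 ± 0.25 and Trib3 0.39 ± 0.36. Kupffer cell markers stood higher without methionine (median 0.31, 11 of 13 positive, adjusted p = 0.00031). Acute phase genes stood higher beside them (0.23, 15 of 20 positive, adjusted p = 0.0040). These lists, and no others here, held without any 1 array. The other 11 that passed were higher for the NF-kB and cytokine list (median 0.38), ER chaperones (0.21), amino acid transporters (0.16), male-biased genes (0.12), ATF4 targets (0.04, adjusted p = 0.042) and clock genes of Dbp phase (0.34), and lower for oxidative phosphorylation (-0.16), tRNA synthetases (-0.24), PPARA targets (-0.27), ribosomal proteins (-0.18) and clock genes of Bmal1 phase (-0.67). Each of them was lost without at least 1 knockout array. Without replicate 1 with methionine, tRNA synthetases (-0.001), PPARA targets (0.015), ribosomal proteins (0.016), oxidative phosphorylation (0.060), male-biased genes (0.13) and transporters (0.41) were lost. Without replicate 2 with methionine it was ATF4 targets (-0.21), transporters (-0.09) and Dbp phase (0.17), and without replicate 1 lacking methionine ATF4 targets (-0.18), Dbp phase (-0.03) and Bmal1 phase (-0.50). Without replicate 2 lacking methionine, ATF4 targets (0.25), transporters (0.34), PPARA targets (-0.10), ribosomal proteins (0.034), oxidative phosphorylation (0.039), ER chaperones (0.22) and cytokines (0.39) were lost, and male-biased genes (0.12) turned lower relative to all genes. ATF4 targets were also lost without any 1 of 4 arrays outside these groups (0.025 each). No member of the 13 lists was called, and with an estimated correlation their adjusted p was 0.82 to 0.92. The knockout unfractionated arrays shared deviations by replicate number between media (r = 0.259 across genes), and with the number as a block 0 genes were called. A fit of these 4 arrays alone called 7 higher and 12 lower genes, and 1 gene was called without knockout unfractionated replicate 1 without methionine.

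The difference between the methionine effects of the genotypes asks which responses depend on Gcn2. In unfractionated RNA, Noct differed by 3.63 ± 0.49 (knockout minus wild-type, SE, 2 arrays per group, adjusted p = 0.0028), from effects of -2.35 in wild-type and 1.28 (not called) in knockout livers. Slc10a2 differed by 2.49 ± 0.40 (adjusted p = 0.018). Its signal was 362.6 ± 52.3 with and 168.4 ± 53.2 without methionine in wild-type livers, and 141.2 ± 27.4 with and 406.1 ± 48.1 without in knockout livers (SD, n = 2 each). Meiob differed by 2.02 ± 0.34 (adjusted p = 0.028). Not called were Trib3 (1.26 ± 0.50), the stress gene Nupr1 (2.83 ± 0.73, adjusted p = 0.57), Apcs (-2.84 ± 0.61, adjusted p = 0.20), Npas2 (-2.35 ± 0.53, adjusted p = 0.27) and Dbp (5.61 ± 1.67, adjusted p = 0.80).

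Relative to all genes, 3 lists stood higher and 6 lower in this difference. The clock genes of Dbp phase (median 1.26, 4 of 9 adjusted over the list alone) stood higher, and those of Bmal1 phase (-1.50) and acute phase genes (-0.58) lower, and these 3 held without any 1 array. The other 6 were each lost without at least 2 arrays. Higher were heat shock (0.45), lost without wild-type replicate 2 with methionine (0.47) or knockout replicate 2 lacking it (0.69), and ATF4 targets (0.23, adjusted p = 0.027, and 0.052 as deposited), lost without any 1 of 7 arrays (0.03 to 0.39). Lower were secreted plasma proteins (-0.18) and drug metabolism (-0.18), which turned to 0.070 and 0.021 without knockout replicate 1 with methionine, female-biased genes (-0.27), which turned to 0.11 without knockout replicate 2 lacking methionine, and cell cycle genes (-0.35), which went to -0.032 without wild-type replicate 2 lacking methionine. Cell cycle and female-biased genes were also lost as deposited (adjusted p = 0.057 each). The adjusted p of the 9 lists was 0.14 to 1.0 with an estimated correlation. By limma 3 genes were called, all higher, with 404 at an unadjusted p under 0.05, and with the signals as deposited 3 were higher and 2 lower. With the replicate number as a block 3 were higher and 4 lower. Without wild-type replicate 1 with methionine 0 were called, without wild-type replicate 2 with methionine, wild-type replicate 2 without or knockout replicate 2 with methionine 1 was called, all unfractionated, and without either wild-type polysome array without methionine 5. Noct was lost without 1 array (wild-type unfractionated replicate 1 with methionine, 3.26), Slc10a2 without any 1 of 5 and Meiob without any 1 of the 8 unfractionated arrays.

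In polysome RNA of wild-type livers the comparison asks which mRNAs gain or lose ribosomes together with their level. Ribosomal protein mRNAs stood lower without methionine, with 0 of 42 tested members positive (9 with the signals as deposited) and 12 called (22 adjusted over the list alone), among them Rpl22 (-1.37 ± 0.24), Rpl38 (-1.20 ± 0.23), Rplp2 (-1.20 ± 0.22) and Rps20 (-1.20 ± 0.23; SE, 2 arrays per group, adjusted p 0.010 to 0.013). Acute phase mRNAs stood higher, with Saa2 at 3.54 ± 0.65, Apcs at 2.38 ± 0.43 and Saa1 at 2.36 ± 0.56 (adjusted p = 0.010, 0.010 and 0.033). Noct fell by -2.34 ± 0.35 (adjusted p = 0.0038), much as in unfractionated RNA. Both wild-type polysome arrays without methionine stood apart from the other 14 arrays on the third principal component (-33.7 and -26.1, the others -10.9 to 17.5), and on the first, which parts the fractions, they lay at 3.9 and 11.5 against 30.7 and 25.5 with methionine, a shift that knockout polysome arrays shared (13.4 and 16.2 against 28.9 and 24.4). Asns (0.07 ± 0.33), Atf4 (0.24 ± 0.25), Ddit3 (-0.03 ± 0.32) and Trib3 (-0.63 ± 0.36) did not pass, nor did Chac1 (0.78 ± 0.30, adjusted p = 0.16), which passed with the signals as deposited (1.09, adjusted p = 0.034).

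The median of all genes was -0.27 in this comparison, 0.02 with the signals as deposited and -0.01 with quantile normalization, so changes of lists are relative to all genes. Ribosomal proteins had a median of -0.67, or -0.40 relative to all genes (adjusted p = 3.7e-10), and -0.36 with the signals as deposited. Nuclear-encoded oxidative phosphorylation genes had 5 of 45 members lower (14 adjusted over the list alone; -0.16 relative to all genes, adjusted p = 0.00086, and 0.056 as deposited), with Ndufa6 (-1.11 ± 0.25) and Cox6c (-1.11 ± 0.24) as examples. The other 21 lists that passed stood higher. The acute phase list had 4 of 20 members called (10 adjusted over the list alone; 1.08 relative to all genes, adjusted p = 2.8e-17), among them Itih4 (1.02 ± 0.27). Secreted plasma proteins (0.57) had 1 of 28 called, Fga (fibrinogen alpha, 0.89 ± 0.21), and 14 called as deposited. Immediate early genes (0.58), bile acid metabolism (0.54), female-biased genes (0.62), drug metabolism genes (0.47, Ces2a called), stellate cell markers (0.37) and amino acid transporters (0.33) also stood higher, and all these lists held without any 1 array. The other 13 lists, among them cytokines (0.69), clock genes of Bmal1 phase (0.83, Npas2 called) and 11 more at 0.11 to 0.40, were each lost without at least 1 array, and the values that follow are plain medians. Among these, proteasome, urea cycle, periportal and NRF2 target genes had medians just below 0 (-0.05, -0.05, -0.02 and -0.16) and above 0 with the signals as deposited and with quantile normalization. Without wild-type polysome replicate 2 with methionine NRF2 targets (-0.42), urea cycle (-0.26), fatty acid synthesis (-0.29), proteasome (-0.13), pericentral (-0.08) and periportal genes (-0.20) were lost. Without replicate 1 with methionine it was cholesterol synthesis (0.05), ER chaperones (0.13), cytokines (0.27), Bmal1 phase (0.35) and endothelial genes (0.21). Without replicate 1 lacking methionine, Bmal1 phase (0.01), endothelial (0.06), urea cycle (-0.02), pericentral (0.11), periportal (0.08) and PPARA target genes (0.03) were lost, and without replicate 2 lacking it NRF2 targets (-0.22), fatty acid synthesis (-0.19) and cell cycle genes (-0.15). NRF2 targets were also lost without any 1 of the 4 knockout unfractionated arrays (-0.16). Calls of Bmal1 phase and endothelial genes were lost as deposited (adjusted p = 0.052 and 0.077), and those of cytokines, cell cycle and endothelial genes with quantile normalization (0.077, 0.063 and 0.14). The adjusted p of the 23 lists was 0.49 to 0.68 with an estimated correlation.

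Beyond the lists, the largest falls were those of 1500011B03Rik (-1.95 ± 0.34), 1700001L05Rik (-1.93 ± 0.39), the glycolysis regulator Pfkfb3 (-1.91 ± 0.49), Uqcr10 of respiratory complex III (-1.89 ± 0.28), Gm16551, Swi5, Lyrm2, Rbis and Nacc1 (-1.70 ± 0.45). Zfp874a (2.27 ± 0.48), Adh6-ps1 (2.01 ± 0.35), Osgin1, a target of the transcription factor NRF2 (1.79 ± 0.35), Gm7969, Birc7, Asic5 and Fgl1 were the largest rises besides the acute phase genes. As deposited, Pfkfb3 (adjusted p = 0.10) and Nacc1 (0.13) were not called.

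By limma, 256 genes passed, 20 higher and 236 lower. With no variance trend 2 were higher and 19 lower, with the mean of probe sets 9 and 65, and with no filter on dim genes 11 and 111. With the signals as deposited 160 were higher and 122 lower, with quantile normalization 189 and 160, and 20 higher and 120 lower genes were called both as deposited and with the scaling used here. The excess of falls depended on single arrays and on the scaling. Without wild-type polysome replicate 2 with methionine 0 were higher and 2 lower, without replicate 1 without it 5 and 0, without replicate 1 with it 22 and 36, and without replicate 2 without it 4 and 236. Without either wild-type unfractionated array with methionine 15 were higher and 113 lower, and without knockout polysome replicate 1 or 2 with methionine 15 higher and 150 or 149 lower. Saa2 was not called without either wild-type polysome array with methionine (2.99 and 4.10) or without replicate 2 without it (2.42), nor Noct without replicate 1 without methionine (-2.10). Every other gene named as called was lost without at least 1 array.

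**Figure D2:**
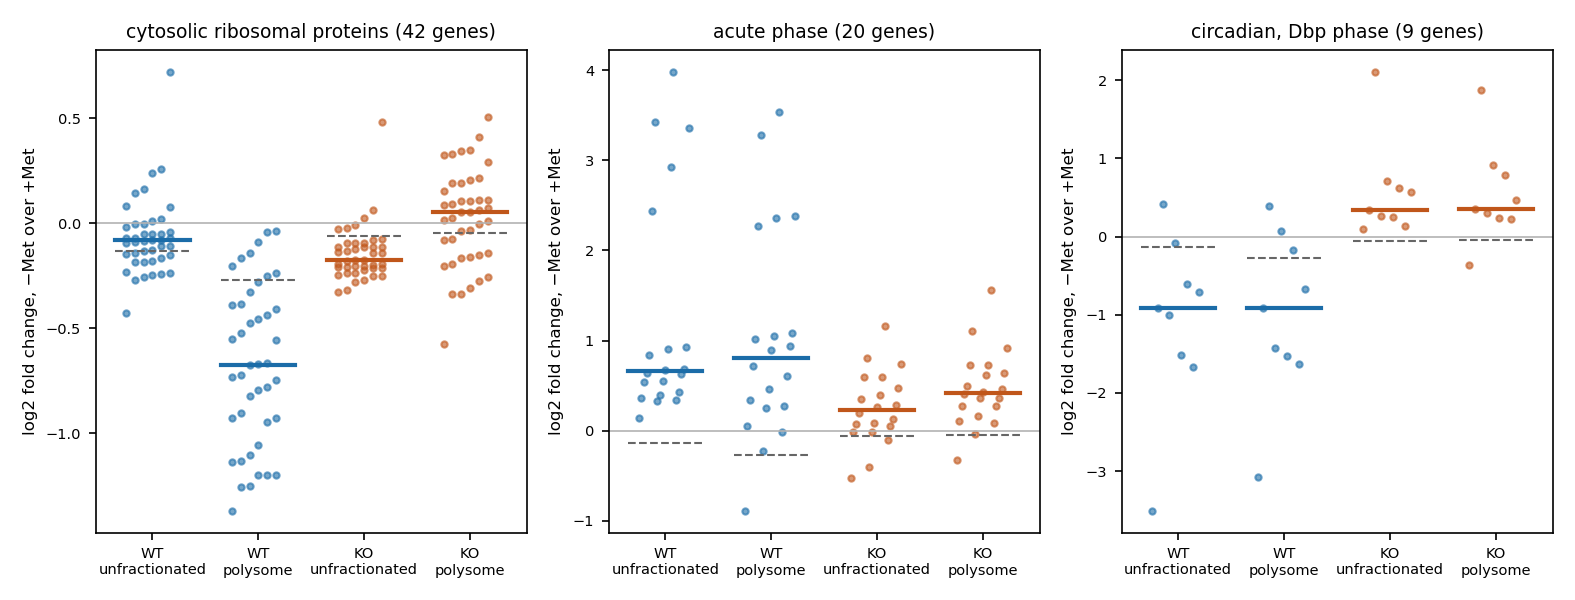
Log2 fold change (without over with methionine) of each tested member of 3 gene lists, ribosomal proteins (42), acute phase (20) and clock genes of Dbp phase (9), in both genotypes and fractions, with the list median (solid line) and the median of all genes (dashed line). The ribosomal protein median was -0.67 in wild-type polysome RNA, and the median of all genes there was -0.27.

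In polysome RNA of knockout livers, Slc10a2 rose without methionine by 2.80 ± 0.28 (SE, 2 arrays per group, adjusted p = 2.1e-05), from 62.9 ± 14.2 to 540.5 ± 156.7 (SD, n = 2 each). The apolipoprotein gene Apoa4 rose by 1.92 ± 0.34 and Mmut fell by -1.47 ± 0.25 (adjusted p = 0.048 each). Kupffer cell markers stood higher (median 0.40, 12 of 13 positive, adjusted p = 3.2e-05), and with them acute phase (0.42) and secreted plasma proteins (0.20). PPARA targets (-0.31) stood lower, while ribosomal proteins did not pass (median 0.06, adjusted p = 0.46). A further 4 lists passed but were lost without single arrays. ER chaperones (0.36) were lost without knockout polysome replicate 1 with methionine (0.15) or replicate 2 lacking it (0.10), male-biased genes (0.15) without the same arrays (0.05 and 0.03), and clock genes of Dbp phase (0.35, and lost as deposited, adjusted p = 0.082) without replicate 2 with methionine (-0.03) or replicate 1 lacking it (0.24). Oxidative phosphorylation (-0.15) was lost without any 1 of 7 arrays (-0.15 to -0.02). The adjusted p of these 8 lists was 1.0 with an estimated correlation. Asns (0.47 ± 0.33), Atf4 (0.55 ± 0.25) and Trib3 (-0.16 ± 0.36) did not pass. By limma 3 genes passed, 2 higher and 1 lower, with 597 at an unadjusted p under 0.05, while 16 were higher and 6 lower with the signals as deposited, and 21 and 6 with quantile normalization. The count was 1 without any 1 of 8 arrays, which were wild-type unfractionated replicates 1 and 2 with methionine, all 4 wild-type polysome arrays, and knockout polysome replicate 2 with and replicate 2 without methionine. Slc10a2 was called in all 31 alternatives, Apoa4 in 14 and Mmut in 13.

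Between the genotypes, the methionine effect in polysome RNA differed for Slc10a2 by 3.64 ± 0.40 (knockout minus wild-type, SE, 2 arrays per group, adjusted p = 8.9e-05) and for Noct by 3.34 ± 0.49 (adjusted p = 0.0049). Gng10, a G protein subunit, differed by 2.40 ± 0.41 (adjusted p = 0.024) and Selenbp1, a selenium-binding protein, by 1.99 ± 0.33 (adjusted p = 0.020, and 0.11 with the signals as deposited). Per1 (2.45 ± 0.54, adjusted p = 0.14) and Dbp (4.95 ± 1.67, adjusted p = 0.37) did not pass. Ribosomal proteins stood higher in this difference, with 41 of 42 members positive (34 as deposited) and 0 called, 16 adjusted over the list alone (median 0.70, or 0.47 relative to all genes, adjusted p = 2.7e-10). PPARA targets stood lower (-0.31, or -0.54 relative to all genes), and both lists held without any 1 array. The other 12 lists were each lost without at least 1 array. Their medians were 1.15 for clock genes of Dbp phase (0.78 and 0.79 without the arrays that ended the call, knockout polysome replicate 2 with and replicate 1 lacking methionine), 0.55 for heat shock (0.38 to 0.61 without any 1 of 4) and -0.91 for clock genes of Bmal1 phase (-0.47 without knockout replicate 1 lacking methionine). Without knockout polysome replicate 1 with methionine, immediate early genes went from -0.38 to 0.055, cytokines from -0.17 to 0.26, proteasome from -0.05 to 0.11 and secreted plasma proteins from -0.02 to 0.05. Without knockout polysome replicate 2 lacking methionine, female-biased genes went from -0.57 to 0.23, fatty acid synthesis from -0.20 to 0.19, urea cycle from -0.14 to -0.003 and drug metabolism from -0.10 to -0.03. Acute phase genes went from -0.23 to 0.04 without wild-type polysome replicate 2 lacking methionine. All these calls were lost there, and heat shock and cytokines also as deposited (adjusted p = 0.080 each). The adjusted p of these 14 lists was 0.70 to 0.79 with an estimated correlation. By limma 4 genes passed, all higher, with 1011 at an unadjusted p under 0.05, and 4 higher and 2 lower with the signals as deposited or quantile normalization. The count was 2 without wild-type polysome replicate 2 with methionine or knockout polysome replicate 1 with methionine, and 1 without wild-type polysome replicate 1 without methionine. Slc10a2 was called in all 31 alternatives, and Noct in 30, lost without wild-type polysome replicate 1 without methionine (3.10).

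The polysome-specific effect of methionine, the part of the polysome change beyond that in unfractionated RNA, asks which mRNAs changed their ribosome loading. Ribosomal proteins stood lower in wild-type livers (median -0.52, or -0.37 relative to all genes, 0 called, 13 lower adjusted over the list alone, adjusted p = 3.0e-11), with Rps20 (-1.28 ± 0.33, SE, 2 arrays per group), Rpl38 (-1.29 ± 0.33) and Rpl22 (-1.30 ± 0.34) as examples, none called. In knockout livers the list had a median of 0.20 and did not pass (adjusted p = 0.073), and the difference between genotypes passed (median 0.77, or 0.59 relative to all genes, adjusted p = 2.2e-12). The ribosomal protein calls in wild-type livers and in the difference held without any 1 array, as did immediate early genes in wild-type livers, which stood higher (median 0.29, or 0.44 relative to all genes). The other 7 lists that passed were lost without single arrays. In wild-type livers proteasome genes (0.08) went to -0.038 without unfractionated replicate 2 with methionine and tRNA synthetases (0.10) to -0.014, while PPARA targets (0.10) went to -0.15 without unfractionated replicate 2 lacking methionine and were lost without any 1 of 4 arrays. In knockout livers secreted plasma proteins (0.18) were lost with quantile normalization (adjusted p = 0.18) and without any 1 of 10 arrays, with -0.062 and -0.068 without unfractionated replicate 1 with or replicate 2 lacking methionine. In the difference immediate early genes (-0.38) went to 0.14 without knockout unfractionated replicate 2 with methionine and to -0.03 without knockout polysome replicate 1 with methionine. PPARA targets (-0.18) and cytokines (-0.48, lost as deposited, adjusted p = 0.13) were each lost without any 1 of 7 arrays (-0.23 to 0.09 and -0.64 to -0.09). With an estimated correlation the adjusted p was 0.87 for the wild-type lists, 0.96 for the knockout list and 0.98 for the lists of the difference. ATF4 targets and the mRNAs with upstream reading frames did not pass in any of the 3 comparisons.

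By limma 0 genes passed in any of these 3 comparisons, with 507 in wild-type livers, 237 in knockout livers and 326 in the difference at an unadjusted p under 0.05. The smallest p-values, none called, were in wild-type livers those of Clcn5 (3.47 ± 0.62, adjusted p = 0.16), Birc7, Zfp276, Dmrtb1 and Ppp1r26 upward and 1700001L05Rik (-2.82), Cep83, Ier3ip1, Apoc2 and Atp5md downward. In knockout livers they were those of Slc12a4, 4933401H06Rik, Coro2b, Gm13889 and Slc10a2 (1.37 ± 0.40), and of Wbscr25 (-2.12), Zc3h8, Otub2, Dclre1b and Sebox. In the difference they were those of Rab7b (3.20), Gm6607, Plcb2, Cep83 and Vhl, and of Sh3bp2 (-4.11), Map11, Clcn5, Birc7 and Sebox. In wild-type livers 1 gene was called without wild-type polysome replicate 1 or replicate 2 with methionine.

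Polysome minus unfractionated RNA over all livers asks which RNAs, coding or not, are richer or poorer in the polysome part of the gradient. Rpl41, a ribosomal protein with a very short reading frame, was lower in polysomes by -4.13 ± 0.13 (SE, 8 arrays per fraction, adjusted p = 1.8e-15), or by -2.60 to -2.47 with another probe set, which became its brightest without any 1 of the 8 unfractionated arrays. Snhg8 (-3.75 ± 0.17), Gas5 (-3.69 ± 0.14), Snhg6 (-3.61 ± 0.18), the mitochondrial ND5 (-3.08 ± 0.16), 2410006H16Rik (-2.75 ± 0.19), Bola3 (-2.71 ± 0.14), Malat1 (-2.47 ± 0.32), Neat1 (-2.43 ± 0.17) and the selenoprotein gene Selenow (-2.33 ± 0.16) were also lower. Without wild-type polysome replicate 1 with methionine another Malat1 probe set became the brightest (-3.65, or -2.91 with the first one kept). Ribosomal proteins had 40 of 42 members lower (median -1.02, adjusted p = 3.8e-46), such as Rps19 (-2.19 ± 0.15) and Rpsa (-2.07 ± 0.13), and 14 of 15 other mRNAs with a TOP motif fell (median -1.01, adjusted p = 1.6e-17), such as Pabpc1 (-2.06 ± 0.14) and Eef2 (-1.22 ± 0.13). Higher in polysomes were Lpp (1.45 ± 0.15), Onecut2, Mfhas1, Bmpr2, Secisbp2l, Arhgef12, Bach2, Lcor and Nfix (1.17 ± 0.15). Zbtb44 (1.20 ± 0.22) depends on the probe set that stands for it, since without any 1 of 4 polysome arrays another of its probe sets became the brightest and was not called (0.23 to 0.28), while the first one, if kept, was (1.00 to 1.12).

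In all, 18 lists stood lower in polysomes and 0 higher. Of 13 Kupffer cell markers 12 fell (median -0.78, adjusted p = 1.7e-09), among them Slc40a1 (-1.52 ± 0.14) and Cd5l (-0.88 ± 0.14). Beside them stood lower stellate cell markers (median -0.52, 7 of 13 called), bile acid metabolism (-0.62, 9 of 13), tRNA synthetases (-0.45, 11 of 21), PPARA targets (-0.33, 7 of 21) and interferon response genes (-0.46, 5 of 12). Calls of secreted plasma proteins (-0.30), urea cycle (-0.37), proteasome (-0.27), male-biased (-0.50), periportal (-0.33), heat shock (-0.38), immediate early (-0.34), serine and one-carbon (-0.32), drug metabolism (-0.32) and cytokine genes (-0.33) were lost with quantile normalization (adjusted p 0.056 to 0.33). The adjusted p of the 18 lists was 0.11 to 0.59 with an estimated correlation, and 15 of them passed fry. By limma 2322 genes passed, 1050 higher and 1272 lower, and 1812 higher and 1617 lower with the signals as deposited. Of these, 1049 higher and 1258 lower genes were called with both scalings, and wild-type arrays alone gave 221 higher and 599 lower, against 499 and 494 in knockout arrays alone. Without 1 array 709 to 1239 were higher and 992 to 1494 lower. Without both wild-type polysome arrays lacking methionine 1154 were higher and 979 lower, and all 18 lists held without any 1 array.

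The methionine effects of wild-type and knockout livers were also set against each other across the 10916 genes, which are not independent replicates. Pearson's r was 0.020 (Spearman 0.026) in unfractionated RNA and 0.156 (Spearman 0.158) in polysome RNA. Among genes called in either genotype r was -0.347 over 8 genes in unfractionated RNA and 0.335 over 259 in polysome RNA, of which 169 had the same sign in both genotypes. With the signals as deposited these were -0.766 over 7 genes and 0.426 over 293 (212 with the same sign), and with quantile normalization -0.782 over 6 and 0.444 over 360 (260 with the same sign). In polysome RNA 58.8% of all genes already had the same sign with the scaling used here, 55.0% as deposited and 54.5% with quantile normalization. Over all genes r was lowest in unfractionated RNA without knockout replicate 2 without methionine (-0.049) and highest without replicate 1 of that group (0.079), and in polysome RNA lowest without wild-type replicate 1 with methionine (0.083) and highest without replicate 2 of that group (0.196). The authors' z ratios correlated with the methionine effects at 0.973 to 0.978 across 8778 genes in both tables.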

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

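The tests of circadian phase, of a methionine response of the clock genes and of array scaling for the ribosomal proteins were chosen after the results were seen, as was the use of the signals as deposited.

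The methionine effect differed between genotypes, by a test of the difference itself, for single genes in both fractions (knockout minus wild-type, log2). In unfractionated RNA these were Noct (3.63), Slc10a2 (2.49) and Meiob (2.02), and in polysome RNA Slc10a2 (3.64), Noct (3.34), Gng10 (2.40) and Selenbp1 (1.99). If the replicate numbers pair the fractions, Noct and Slc10a2 passed in both on the same pools, which are not independent results. The same test with the preset correlation between genes passed for several lists, given here as medians. In unfractionated RNA they were clock genes of Dbp phase (1.26), clock genes of Bmal1 phase (-1.50), acute phase (-0.58), heat shock (0.45), cell cycle (-0.35), female-biased genes (-0.27), ATF4 targets (0.23), secreted plasma proteins (-0.18) and drug metabolism (-0.18). In polysome RNA they were ribosomal proteins (0.70), clock genes of Dbp phase (1.15), clock genes of Bmal1 phase (-0.91), female-biased genes (-0.57), heat shock (0.55), immediate early genes (-0.38), PPARA targets (-0.31), acute phase (-0.23), fatty acid synthesis (-0.20), cytokines (-0.17), urea cycle (-0.14), drug metabolism (-0.10), proteasome (-0.051) and secreted plasma proteins (-0.022). In the polysome-specific effect they were ribosomal proteins (0.77), immediate early genes (-0.38), PPARA targets (-0.18) and cytokines (-0.48). Without any 1 array only the clock and acute phase lists in unfractionated RNA, ribosomal proteins and PPARA targets in polysome RNA and ribosomal proteins in the polysome-specific effect held. None of these lists passed with an estimated correlation.

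The methionine effect on the clock lists differed between genotypes, with shifts in opposite directions that passed for both lists in unfractionated RNA, while in polysome RNA the Dbp-phase list in wild-type (adjusted p = 0.078) and the Bmal1-phase list in knockout livers (0.21) did not pass. A candidate explanation is that the pools differed in circadian phase whatever the medium. In 8 of 8 pairs of same-group arrays the Dbp-phase and Bmal1-phase lists did differ in opposite directions. If the replicate numbers pair the fractions, which are then not independent, this is 4 pairs of pools. A methionine response that depends on Gcn2 stays open, because the difference between genotypes in the Dbp-phase list exceeded the largest difference between arrays of one group (0.851) in both fractions (1.199 in unfractionated and 0.916 in polysome RNA, relative to all genes), but by less than the spread of those differences (root mean square 0.54). Some of these calls were lost without 1 array, as that of the Dbp-phase list in knockout unfractionated RNA without replicate 1 lacking methionine (-0.027) or replicate 2 with it (0.17), and that of its difference in polysome RNA without knockout polysome replicate 2 with methionine (0.78) or replicate 1 without it (0.79). Noct and Per1, which also cycle in liver, belong to the same question.

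Ribosomal protein mRNAs stood lower in wild-type polysomes without methionine, in the arrays that stood apart from the other 14 on the third principal component (-33.7 and -26.1). The tables argue against array scaling, 1 deviating array and a shift of all mRNAs with low polysome association as the whole cause, the last with the scaling used here alone. With quantile normalization the list still passed (adjusted p = 1.26e-11), although its own median went from -0.67 to -0.41 (-0.36 and 9 of 42 members positive with the signals as deposited), so scaling can account for part of the fall, and without any 1 of the 4 wild-type polysome arrays it passed too (highest adjusted p = 1.76e-05). A shift of all mRNAs with low polysome association should have lowered other such mRNAs as well. Instead, 1085 genes, the lowest 10% of other genes by polysome minus unfractionated RNA in knockout arrays, shifted the other way by 0.27 relative to all genes. This was -71.6% of the shift of the ribosomal proteins (-0.37). Their median in knockout arrays was -0.64, against -0.74 for ribosomal proteins. Knockout arrays alone called 494 genes lower in polysomes, so not all of the 1085 were shown to be low. The shift was not computed with other scalings. The genes were not chosen by how many ribosomes their mRNAs carry. The test therefore cannot tell whether another division of the gradient lost mRNAs with few ribosomes. A technical difference shared by both of these arrays was not tested and stays open, as does a response to methionine that needs Gcn2, since the list did not pass with an estimated correlation (adjusted p = 0.49 in wild-type polysomes), and further pools measured in every part of the gradient would tell them apart.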

How the results depend on the processing

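The signals as deposited were added after the array medians were seen, and leaving out both wild-type polysome arrays without methionine after they were seen to stand apart. Keeping the main probe set of named genes when an array was left out was added last, and all other alternatives were planned. Among called named genes, leaving out 1 array kept 2501 calls and ended 295, and the other settings kept 2621 and ended 301, with 1 reversed. Among list shifts the same figures were 1713, 174 and 1 reversed, and 534, 289 and 3 reversed. Named genes that had not passed did so in 40 cases without 1 array and in 159 cases in other settings. The probe set that stands for a gene was chosen anew without each array, and it changed for 11 named genes in 1 or more of these fits. The causes were not tested, except where a setting uses fewer arrays, more genes or another threshold. At most 28.5% of probe sets reached a signal of 80, and fold changes of dimmer genes are limited by background and shrunk by the offset.

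The Gcn2 level, -0.89, was not called as a mean of probe sets (-0.45, adjusted p = 0.079), without methionine alone (-0.62, 0.27) or in polysome arrays alone (-0.74, 0.15), and with the dimmest 60% left out it was not tested. Counts of called genes that moved by more than 1.5 times follow by setting. With quantile normalization, knockout polysomes gave 27 and genotype 498, and within each fraction they gave 24 and 485 and the unfractionated difference between genotypes 5. With the signals as deposited the counts were 22 for knockout polysomes, 456 for genotype and 5 for the unfractionated difference. With an offset of 1 knockout polysomes gave 1. With no filter on dim genes wild-type unfractionated RNA gave 1, the unfractionated difference 1, wild-type polysomes 122, knockout polysomes 1 and the polysome difference 2. With no variance trend they gave 0, 1, 21, 1 and 2, and the polysome-specific effects gave 1 in wild-type and 1 in knockout livers. With the replicate number as a block the unfractionated difference gave 7, wild-type polysomes 390 and the polysome-specific effect in wild-type livers 1. With every probe set tested knockout polysomes gave 1, genotype 430 and polysome minus unfractionated 3798. With the mean of probe sets wild-type unfractionated RNA gave 2, wild-type polysomes 74, knockout polysomes 1, the polysome difference 2 and the polysome-specific difference 1. At a threshold of 0.1 the unfractionated difference gave 5, wild-type polysomes 592 and genotype 441. With the arrays of the compared groups alone knockout unfractionated RNA gave 19, wild-type polysomes 168, knockout polysomes 1 and the polysome difference 2. Genotype gave 136 with methionine, 150 without, 79 in unfractionated and 155 in polysome arrays, and polysome minus unfractionated 820 in wild-type and 993 in knockout arrays.

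Of the 118 list shifts 0 passed with an estimated correlation and 15 with fry. The correlation of wild-type and knockout methionine effects was -0.347 over called genes in unfractionated RNA, and in polysome RNA 0.335 over called genes, 0.127 with quantile normalization and 0.098 with no filter. Reversed were Hsd3b5 in the genotype effect without methionine (0.017) and, with fry, the urea cycle (-0.050), NRF2 (-0.16) and proteasome (-0.046) lists in wild-type polysomes. The male-biased list in knockout unfractionated RNA reversed in the test without knockout replicate 2 without methionine (median 0.12, and 0.12 to 0.17 over all arrays left out in turn).

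Leaving out 1 array at a time, the ranges were 0 to 11 for wild-type and 0 to 1 for knockout unfractionated RNA, 0 to 5 for their difference, 2 to 337 for wild-type and 1 to 3 for knockout polysomes and 1 to 6 for their difference. They were 0 to 1, 0 to 0 and 0 to 0 for the polysome-specific effects in wild-type and knockout livers and their difference, 194 to 377 for genotype, 1745 to 2326 for polysome minus unfractionated, -0.998 to -0.784 for the Gcn2 level and 106 to 135 for list shifts. The correlations ran from -0.049 to 0.079 in unfractionated and from 0.083 to 0.196 in polysome RNA. A group left with 1 array is assumed to vary like the others.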

Other observations

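The tests for neighbouring genes and the test of 1 other probe set per gene were chosen after the results were seen, while the splits of the pools and the test of all other probe sets were planned.

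Several genes with large differences between genotypes lay together on chromosomes. On chromosome 19, 7 of 8 tested genes in the Cyp2c block differed, among them Cyp2c39 (3.67 ± 0.16) and Cyp2c37 (-2.33 ± 0.57). On chromosome 1, 6 of 13 tested genes in a row were called, among them Atf6, Dusp12 and Cfap126, on chromosome 7 it was 4 of 10 (Aen, Isg20, Abhd2 and Ap3s2) and on chromosome 9 it was 4 of 9 (Wdr82, Ppm1m, Alas1 and Abhd14a). Around Gcn2 itself 3 of 60 neighbours were called, Ccdc32 (-0.75), Chac1 (0.72) and Exd1 (1.19), against a median of 1 and a 95th percentile of 5 in windows of that size.

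These blocks may reflect strain alleles that differ between the pooled mice of both genotypes. Neither the use of littermates nor the surroundings of Gcn2 (3 of 60 neighbours called, 95th percentile 5) speaks for this, so it stays a candidate. Called genes made 21 adjacent pairs, like-named neighbours left out, against a mean of 6.5 and at most 16 in 1000 random placements. Shared regulation of neighbours in general was not decided. As many genes of the polysome comparison made 5 pairs. Those of the 9 methionine comparisons made 2 to 11, the highest at the 95th percentile of its random placements (11). But the polysome comparison sets fractions of the same livers against each other, and most methionine comparisons called few genes. Sharing could hardly have shown there. The methionine effect in wild-type polysome RNA, with 256 genes called, made 8 pairs. Sequence variants under single probe sets are argued against as the cause for all these genes, since the brightest other probe set went the same way with an unadjusted p under 0.05 in 68.4% of 19 called genes in adjacent pairs (95% exact binomial interval 43.4% to 87.4%), against 8.8% of genes not called, although direction alone did not decide (84.2%, interval 60.4% to 96.6%, against 68.8%). For part of the genes such variants stay open, as 55% of all other probe sets of called genes did so (interval 47.8% to 62.0%, which spans the bound of 50%, and 60.3% for polysome minus unfractionated RNA, where variants play no part), and so does loss of Gcn2 for each single gene, Asns included.

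Chance is an unlikely source of the number of genotype differences at the level of the pools inferred from the replicate numbers, but is not excluded. Of 35 splits of the 8 pools into 4 and 4, 1 gave as many genes, the real one, with 232 genes against 33 at most in the others. With 35 splits, 1 in 35 is the lowest share that this test can reach. For polysome minus unfractionated RNA, 1 of 100 splits that part the arrays of every pool gave as many, with 2478 genes against 1315 at most. In both tests the real difference stays in the residual spread of the other splits, which can lower their counts.

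Lists that passed in 0 comparisons were methionine cycle and transsulfuration (22 tested genes), mRNAs with upstream reading frames (13), metallothioneins and hypoxia (12) and the genes near Gcn2 (40). In the methionine cycle list the medians of the methionine effect were -0.02 and -0.08 in unfractionated RNA of wild-type and knockout livers, and -0.11 and -0.03 in polysome RNA.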
